A study of Mus musculus with 18 samples.

How the data were processed

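Affymetrix Mouse Exon 1.0 ST arrays, which read most exons of each gene with separate probe sets, were hybridised with total RNA of spinal cord, brain and kidney from mice with spinal muscular atrophy (SMA) and from control mice at postnatal day 11. The labels give 3 SMA and 3 control arrays per tissue and 18 arrays in all, and call the controls unaffected littermates. SMA follows from loss of the survival motor neuron gene, Smn1 in the mouse. The allele of these mice is not given in the sources used here. The labels speak of separate mice within a group. They do not state that arrays with the same number in different tissues came from the same mouse.

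The deposited table holds 1 log2 value per probe set and array. RMA (robust multi-array average, which subtracts background, sets all arrays to one distribution and summarises probes) and Partek are named in the submitters' processing notes, with no version and no role. The array medians of these log2 values, which the authors made, were 5.61 to 5.64 in spinal cord, 7.53 to 7.55 in brain and 7.55 to 7.56 in kidney. The spinal cord arrays were therefore set to another distribution than the others, and levels are not tested between tissues. Marker levels are given per tissue only to describe the arrays. Changes between SMA and control were taken within each tissue, where all 6 arrays share a distribution. Array files carry a hybridisation day and a wash station. All arrays of a tissue were run on 1 day, so a block on the day was not possible.

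Of 193380 probe sets, 178677 have 1 gene symbol in the platform annotation, 1315 have several and 13388 are not listed there. Probe sets with 1 symbol gave 15726 genes with a median of 9 probe sets. Of these symbols 13662 are current in the RefSeq table of GRCm38.p6, 2059 are older synonyms and 5 are in neither group. Symbols are printed as the annotation gives them. Exon numbers and coordinates of probe sets were not used here, so a probe set is named by its identifier.

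A gene's value was the mean of the log2 values of its probe sets. SMA minus control was fitted per tissue with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Every adjusted p of a single gene below comes from this limma model unless another is named. Gene lists (32 in spinal cord and brain, 31 in kidney) were tested with camera of limma, which asks whether a list moved more than the other genes, at a preset correlation of 0.01, and again with a correlation estimated per list. Probe sets were tested against the other probe sets of their gene with diffSplice of limma, in genes at or above the median gene, over probe sets above the 25th percentile, with at least 4 left per gene. The splicing index, the probe set minus its gene on the same array, was the alternative. Differences of the SMA effect between tissues were tested as contrasts of contrasts over all 18 arrays. The spinal cord arrays were hybridised on another day than the brain and kidney arrays and set to a wider distribution. In a difference that involves spinal cord, day and distribution therefore cannot be told apart from the tissue. Random blocks used statmod 1.5.0. An exact test of 3 against 3 arrays cannot go below p = 0.1, and no rank test was used.

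The lists of the report, the main tests and most alternatives were fixed before the data were examined. The wash station block, the splicing index with a trend and robust prior, the tests of the closing section and their lists (meninges, heat shock and PPAR-alpha targets) were added later. Fixed in advance too was the rule for named genes: Smn1, the 10 largest rises and 10 largest falls past the threshold with non-overlapping groups, up to 4 members of each list with the smallest p, the 10 probe sets with the largest relative change, and 6 genes per pair of tissues with the smallest adjusted p. Predicted genes and olfactory receptors were left out of the ranking of rises and falls. Hoxc8, Tbr1, Brd3, Ephb3, Rgnef, Ehhadh, Pcolce, Islr, Cyp4a10, Acot1 and the kidney value of Cirbp fall outside this rule and were chosen after their values were seen.

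On simulated data the gene test found 94.0%, 97.0% and 97.0% of 67 genes changed by 1 on the log2 scale in spinal cord, brain and kidney, and 34.3%, 16.4% and 37.3% of 67 genes changed by 0.5, with 7, 9 and 13 unchanged genes called. The diffSplice test was not calibrated on the same kind of data: it called 343, 110 and 153 unchanged probe sets, while the splicing index called 3, 8 and 6. Simulated probe sets varied independently, and those counted as unchanged include probe sets of genes that held a changed one. These numbers are therefore not error rates of the real arrays. The splicing index found 54.5%, 97.0% and 98.5% of 66 probe sets changed by 2 on the log2 scale. It found 0%, 26.9% and 25.4% of 67 changed by 1, and 0% of 67 changed by 0.5 in each tissue. A list shifted by 0.5 was called in each tissue, with 0 of the other lists called. The simulated genes varied independently of each other, so this does not show how often lists of correlated genes are called wrongly. Other splits of the real arrays gave up to 14, 6 and 11 called lists.

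Same-numbered SMA and control spinal cord arrays deviated together from their group means (r = 0.47, 0.33 and 0.45 across genes, which are not independent replicates). By the rule fixed in advance, all 3 above 0.1, the numbers pair the spinal cord arrays, and the value with the replicate number as a block stands beside a result it changes. The correlations were -0.04, -0.25 and 0.09 in brain and -0.01, 0.01 and -0.01 in kidney, where the numbers do not pair the arrays.

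Wash station 1 held 1 SMA and 1 control spinal cord array, and station 2 held 2 and 2. In brain and kidney only station 1 held both groups, with 1 SMA and 1 control array, so a station block there rests on that pair. In each tissue the arrays on station 1 were SMA replicate 3 and control replicate 1. Of these the control array alone carried Y-linked signal, so within station 1 sex cannot be told apart from SMA. Alternatives covered the summary of probe sets, filters on dim probe sets and genes, renormalization, moderation, the samples in the fit, blocks, and each array left out. The precision of every value is limited by 3 arrays per group.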

Results

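The series measured exon-level expression in spinal cord, brain and kidney, with 3 SMA and 3 control mice per tissue, 11 days after birth. The design asks which genes and exons differ in the affected spinal cord, and whether the same changes occur in brain and in kidney, a tissue outside the nervous system. Control arrays carried the markers of their labelled tissue. Hoxc8, a gene of posterior body segments, read 8.48 ± 0.15 (SD, n = 3) in control spinal cord and 5.42 ± 0.07 in brain on the log2 scale, and Tbr1, a cortical transcription factor, read 4.03 ± 0.09 and 9.30 ± 0.26. Proximal tubule markers averaged 11.02 in control kidney, 3.89 in spinal cord and 5.20 in brain. Arrays of 1 tissue correlated at 0.972 to 0.982 in spinal cord, 0.969 to 0.981 in brain and 0.964 to 0.982 in kidney across probe sets, which are not independent replicates.

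Smn1, the gene lost in SMA, fell in all 3 tissues. The log2 change was -0.92 ± 0.14 (SE, 3 arrays per group) in spinal cord, -1.78 ± 0.17 in brain and -1.51 ± 0.12 in kidney, with adjusted p of 0.0217, 0.0269 and 0.00111 in limma. The SMA means in brain (5.05) and kidney (5.06) lay under the 25th percentile of the arrays, so these 2 sizes are uncertain. Of its 10 probe sets, 9, 9 and 10 were lower in SMA. Probe set 5588437 had changes of -2.12, -3.31 and -3.44, while 4344871 had -0.45, 0.09 and -0.44. In SMA probe set 5588437 read 3.05, 3.94 and 3.91, under the 25th percentile of the arrays in each tissue, so background may understate its changes. Which part of the gene the allele alters, and where these probe sets lie, is not used here, so a probe set outside that part checks nothing about the labels. With the wash station as a block the changes were -0.92, -1.37 and -1.44 (adjusted p = 0.0520, 0.884 and 0.0847), and within station they were -1.27 and -0.75 on stations 1 and 2 in spinal cord, -1.37 on station 1 in brain and -1.44 on station 1 in kidney. In spinal cord the adjusted p passed 0.05 without SMA replicate 1 (-0.90), SMA replicate 3 (-0.82), control replicate 1 (-0.85), control replicate 2 (-1.02) or control replicate 3 (-0.90). In brain it did so without SMA replicate 1 (-1.71), 2 (-1.71) or 3 (-1.92), control replicate 1 (-1.84) or control replicate 2 (-1.63), and with the replicate block (adjusted p = 0.122). From the median of the probe sets the changes were -1.46, -2.08 and -2.09 (adjusted p = 0.0432, 0.117 and 0.00176), and from probe sets above the 25th percentile alone -1.18, -0.67 and -0.94 (adjusted p = 0.0321, 0.154 and 0.00868).

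**Figure D1:**
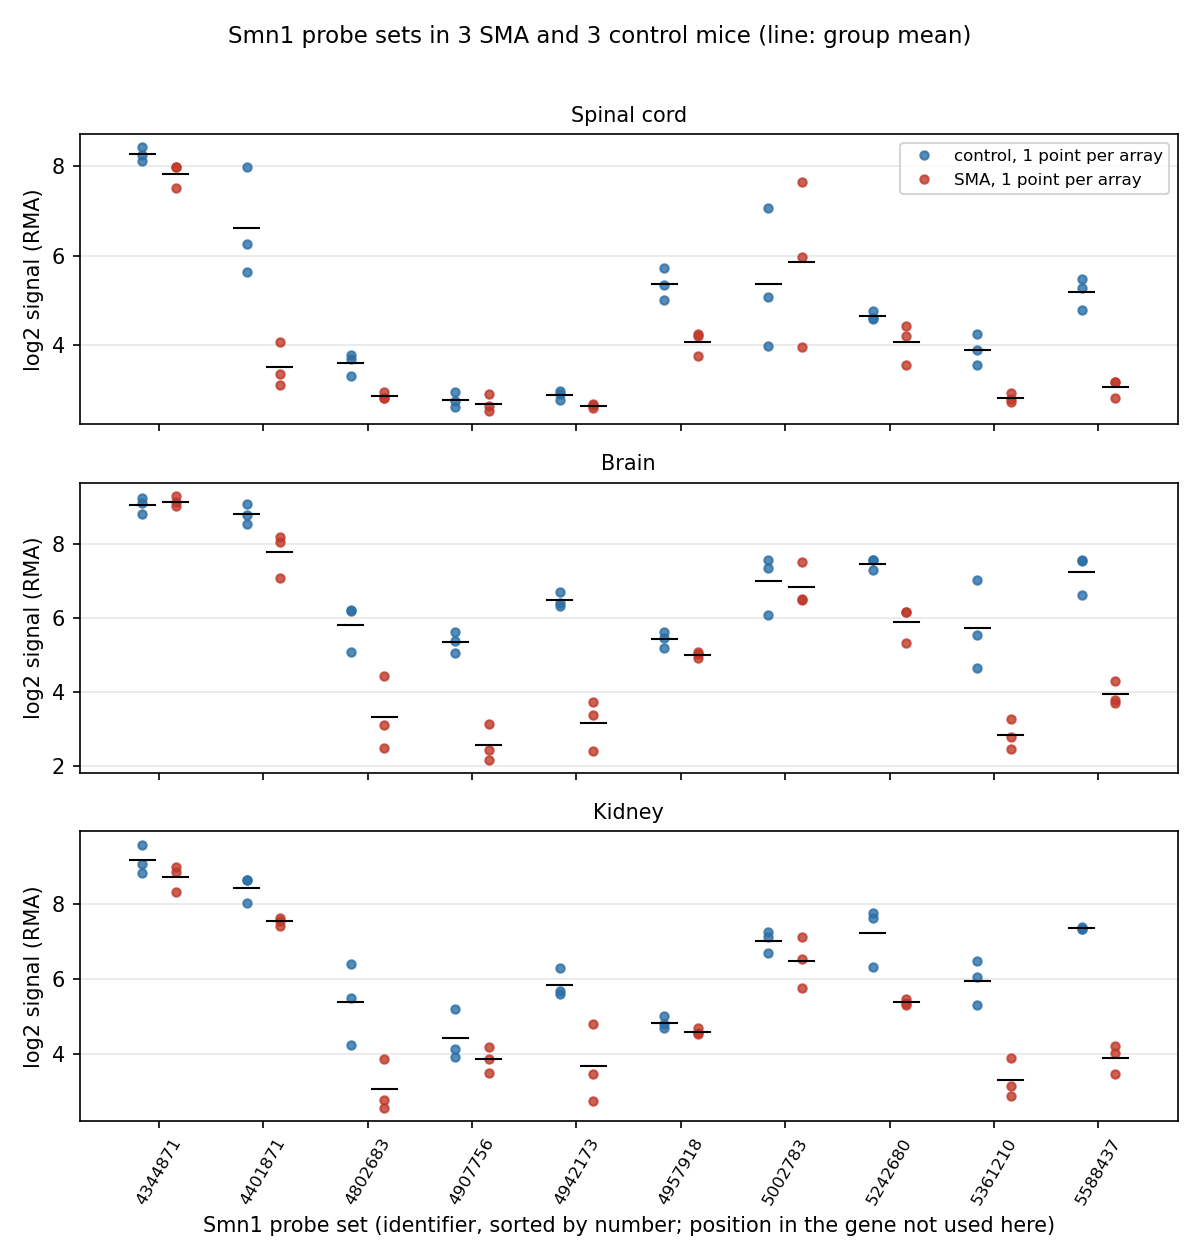
Log2 RMA signal (vertical axis) of the 10 Smn1 probe sets (horizontal axis, sorted by identifier) in spinal cord, brain and kidney, with 1 point per array, blue for control, red for SMA and a line at the mean of 3 arrays. Probe set 5588437 is lower in SMA by 2.12, 3.31 and 3.44 in the 3 tissues, and 4344871 differs by at most 0.45.

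In SMA spinal cord motor neuron and connective tissue genes fell, and genes induced by glucocorticoids and fasting rose. Chodl, which codes for chondrolectin and is enriched in fast motor neurons, had the largest fall, -2.32 ± 0.09 (SE, 3 arrays per group) with an adjusted p of 0.000225. It was followed by the thrombomodulin gene Thbd (-1.86 ± 0.23), the collagen genes Col15a1 (-1.81 ± 0.26), Col3a1 (-1.64 ± 0.17) and Col1a1 (-1.62 ± 0.24), the insulin-like growth factor binding protein gene Igfbp4 (-1.72 ± 0.14), and Rcn3, Tgfbi, Slc38a5 and Angptl2 (-1.61 to -1.54). The largest rise was that of Fam107a (2.77 ± 0.20), an actin-binding protein gene, followed by the glucocorticoid receptor co-chaperone gene Fkbp5 (2.26 ± 0.15), the cell cycle inhibitor gene Cdkn1a (1.73 ± 0.23), Slc2a4 for the insulin-responsive glucose transporter (1.63 ± 0.16), Sult1a1 (1.44 ± 0.09), the angiotensinogen gene Agt (1.42 ± 0.20), Txnip (1.35 ± 0.17), Pla2g3 (1.31 ± 0.12), the cold-inducible RNA-binding protein gene Cirbp (1.24 ± 0.17) and Hist1h1c (1.22 ± 0.23). The adjusted p of these 20 genes lay between 0.000225 and 0.0458.

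Over all 15726 genes, 387 changed in spinal cord by limma, 142 up and 245 down, and 79 of them by at least 2-fold. With the replicate number as a block, which pairs these arrays, 1090 changed (452 up, 638 down), including all 387. With the wash station as a block 209 changed, 204 of them among the 387. Each array counted: 60 genes changed without SMA replicate 2, 123 without SMA replicate 3, 129 without control replicate 1, 118 without control replicate 2, 87 without control replicate 3 and 273 without SMA replicate 1. Medians of probe sets gave 54 genes, a model with no moderation gave 7, and all 18 arrays in one model gave 913. The SMA and control arrays did not overlap for 19.4% of all genes, where chance gives 10%.

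Fibroblast and matrix genes fell as a group in spinal cord, 13 of 17 measured members, with a median change of -1.04. Besides Igfbp4 they included Lum (-1.48 ± 0.12), Dcn (-1.42 ± 0.13) and Ogn (-1.17 ± 0.10), which code for small matrix proteoglycans. Adjusted over the list alone 15 fell, and the camera test gave an adjusted p of 7.16e-22. Of the motor neuron list 7 of 18 members fell, and 10 adjusted over the list alone (median -0.59, adjusted p = 5.12e-11). They included Chodl, the intermediate filament gene Prph (-1.27 ± 0.08), Mmp9 (-0.71 ± 0.08) and the acetylcholine-synthesising enzyme gene Chat (-0.70 ± 0.09). Chodl also stands in a list of candidate splice genes taken from SMA literature. Lists of the vessel wall were also called down, at the preset correlation alone. Of the endothelium list 5 of 16 fell (10 fell and 1 rose adjusted over the list alone, median -0.43), among them the receptor genes Tek (-0.77 ± 0.12), Kdr (-0.71 ± 0.12) and Flt1 (-0.62 ± 0.12). The endothelial adjusted p of 4.72e-07 became adjusted p = 0.368 with an estimated correlation. Of the pericyte list 1 of 11 fell, Rgs5 (-0.70 ± 0.11), also 1 adjusted over the list alone (camera adjusted p = 0.00689, and adjusted p = 0.544 with an estimated correlation). Of the Schwann cell list 1 of 9 fell, the shared member Prph, and 5 adjusted over the list alone (median -0.66, camera adjusted p = 1.27e-05, and adjusted p = 0.368 with an estimated correlation).

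Of the cell cycle list 9 of 25 members fell in spinal cord, and 17 adjusted over the list alone, with a median of -0.40. Top2a (-1.10 ± 0.13, with the SMA mean at the 25th percentile of the arrays), Prc1 (-0.91 ± 0.09), Tpx2 (-0.91 ± 0.11) and Ccna2 (-0.75 ± 0.09), genes of replication and mitosis, led them. The camera adjusted p was 3.70e-17, and adjusted p = 0.0983 with an estimated correlation. Of the glucocorticoid and fasting list 9 of 17 rose (15 rose and 1 fell adjusted over the list alone, median 1.06, adjusted p = 4.29e-17), including the metallothionein gene Mt1 (1.11 ± 0.11) and the kinase gene Sgk1 (0.92 ± 0.11) beside Fkbp5 and Sult1a1. Of the p53 target list 5 of 23 rose, and 12 adjusted over the list alone (median 0.33, adjusted p = 2.85e-10). They were led by Cdkn1a, which the glucocorticoid list also holds, the apoptosis gene Pmaip1 (1.00 ± 0.15), Trp53inp1 (0.84 ± 0.14) and the DNA polymerase gene Polk (0.68 ± 0.12). In the list of the insulin-like growth factor axis Igfbp4, Igfbp2 (-1.07 ± 0.12) and H19 (-0.97 ± 0.11) fell and Igfbp3 (0.82 ± 0.10) rose, 4 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.000972, and adjusted p = 0.129 with an estimated correlation). The astrocyte list was called up at the preset correlation, with 2 of 17 rising, Fgfr3 (0.56 ± 0.09) and Gjb6 (0.88 ± 0.17), while 7 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0138, and adjusted p = 0.496 with an estimated correlation). Of the clock list Per1 (1.10 ± 0.15) and Nfil3 (0.83 ± 0.14) rose among 15, and 4 adjusted over the list alone (camera adjusted p = 0.0119, and adjusted p = 0.386 with an estimated correlation). Of the cholesterol synthesis list 0 of 19 passed limma over all genes and 2 fell adjusted over the list alone (median -0.21, camera adjusted p = 6.70e-05, and adjusted p = 0.372 with an estimated correlation).

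In all, 12 of 32 lists were called in spinal cord, and 4 with an estimated correlation: fibroblast and matrix (adjusted p = 0.0116), glucocorticoid and fasting (0.0116), motor neuron (0.0272) and p53 targets (0.0371). Within wash stations 1 and 2 the medians were -1.19 and -1.0 for fibroblast and matrix, -0.35 and -0.62 for motor neuron, -0.39 and -0.40 for cell cycle, 0.92 and 0.88 for glucocorticoid and fasting, and 0.52 and 0.30 for p53 targets. They were -0.60 and -0.39 for endothelium, -1.06 and -0.36 for Schwann cell, -0.37 and -0.20 for pericyte, -0.26 and -0.18 for the growth factor axis, 0.41 and 0.19 for astrocyte, 0.01 and 0.27 for clock, and -0.04 and -0.23 for cholesterol. The other 20 lists were not called, the nearest being spliceosome proteins (adjusted p = 0.0503). General neuron and synapse, myelin, microglia and SMN complex genes were among these 20, with medians of 0.05, 0.02, 0.02 and 0.03.

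In SMA brain few single genes passed, and they were mostly ones that rose. By limma 6 of 15726 genes changed, and 1730 had an unadjusted p under 0.05. Besides Smn1, which fell, Agxt2l1, now named Etnppl and coding for an enzyme of phosphoethanolamine breakdown, rose by 1.5 ± 0.12 (SE, 3 arrays per group). The metallothionein gene Mt2 (1.18 ± 0.12), Txnip (1.18 ± 0.11), 4921511C20Rik (1.15 ± 0.11) and Plekhf1 (1.10 ± 0.11) rose too, with adjusted p between 0.0197 and 0.0286. The next by p, Cirbp (0.90 ± 0.11), Uhrf1 (-1.08 ± 0.13), Fkbp5 (0.96 ± 0.12) and Slc2a4 (1.14 ± 0.14), had an adjusted p of 0.0589. The control means of Agxt2l1 and Plekhf1 lay under the 25th percentile of the brain arrays, so their sizes are uncertain, and both means of 4921511C20Rik did, so its size is not reliable. Txnip, which binds thioredoxin and limits glucose uptake, and Smn1 were the 2 genes called in all 3 tissues. The brain count was 0 with the replicate block (1372 at unadjusted p under 0.05), 1 with the wash station as a block (737), 0 with no moderation (1646) and 0 from probe sets above the 25th percentile (1684). Without SMA replicate 1 it was 1 (1509), without SMA replicate 2 it was 0 (1750), without SMA replicate 3 it was 0 (1239), without control replicate 1 it was 0 (1398), without control replicate 2 it was 0 (1669), and without control replicate 3 it was 8 (1280), all by limma. It was 31 among genes at or above the median gene, 41 with a trend and robust prior, 187 with all 18 arrays in the model and 1 from medians of probe sets. The groups did not overlap for 17.5% of genes, where chance gives 10%.

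Gene groups moved in brain where few single members passed. All 17 members of the glucocorticoid and fasting list were higher in SMA brain, with a median of 0.52, and 2 rose over all genes and 14 adjusted over the list alone. It was the 1 list of 11 called by camera (adjusted p = 4.18e-18) that held with an estimated correlation (adjusted p = 0.0236). Of the cell cycle list 23 of 25 members were lower (median -0.44), with 0 past limma over all genes and 15 falls adjusted over the list alone (camera adjusted p = 4.18e-18, and adjusted p = 0.210 with an estimated correlation). Top2a had a change of -1.36 ± 0.22 and Mki67 of -0.93 ± 0.19, uncertain in size since their SMA means lay under the 25th percentile of the brain arrays. The p53 target list had a median of 0.27 with 0 past limma over all genes and 10 rises adjusted over the list alone (camera adjusted p = 4.77e-06, and adjusted p = 0.0891 with an estimated correlation), and Eda2r had 1.05 ± 0.15 with both means under that percentile, so its size is not reliable. Endothelium (median -0.24, 0 and 2 falls adjusted over the list alone), fibroblast and matrix (-0.16, 0 and 5 falls) and immediate early genes (-0.19, 0 and 3 falls) were called down, each with adjusted p = 0.210 with an estimated correlation. Cholesterol synthesis (median -0.15) was called down, and astrocyte (0.25), skeletal muscle (0.19), mitochondrial respiratory chain (0.12) and clock genes (0.15) were called up, each with adjusted p = 0.303 with an estimated correlation. Of these 5 lists 0 members passed limma over all genes, and adjusted over the list alone 3 astrocyte genes rose and 1 fell and 1 muscle gene rose. The muscle list averaged 5.47 in control brain, at the 25th percentile of the arrays (5.46 to 5.55), so its size is not reliable. On wash station 1, the station that held both groups, the medians were 0.59 for glucocorticoid and fasting, -0.53 for cell cycle, 0.22 for p53 targets, -0.18 for endothelium, -0.09 for fibroblast and matrix, -0.13 for immediate early, -0.17 for cholesterol, 0.19 for astrocyte, 0.17 for skeletal muscle, 0.08 for mitochondrial and 0.18 for clock genes. The motor neuron list was not called in brain (median 0.09, adjusted p = 0.431), nor were the other 20 lists.

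In the model without a block, SMA kidney had the most changed genes of the 3 tissues. Cyp27b1, which makes active vitamin D, rose by 4.48 ± 0.24 (SE, 3 arrays per group), 22.2-fold with an adjusted p of 0.000222. Acnat2 (2.42 ± 0.16), Abca8a (2.41 ± 0.20), Fkbp5 (2.35 ± 0.11), the fatty acid hydroxylase gene Cyp4a14 (2.08 ± 0.08), the glycine decarboxylase gene Gldc (2.06 ± 0.13), Rasgef1b (2.05 ± 0.10), Abca6 (1.89 ± 0.10), the lipoprotein lipase inhibitor gene Angptl4 (1.87 ± 0.14) and the sulfotransferase gene Sult1d1 (1.70 ± 0.12) followed. The largest falls were those of the steroid dehydrogenase gene Hsd3b2 (-2.90 ± 0.13), Osta for a subunit of the organic solute transporter (-2.85 ± 0.14), the anion transporter gene Slc17a3 (-2.36 ± 0.23), the erythropoietin gene Epo (-2.27 ± 0.11) and Dio1, whose enzyme activates thyroid hormone (-2.09 ± 0.15). Angptl7, Chrna4, Ces1, Defb19 and Fam151a fell by 1.99, 1.89, 1.84, 1.83 and 1.74. The adjusted p of these 20 genes lay between 0.000153 and 0.00442. The lower group mean of Cyp27b1, Abca8a, Abca6, Epo and Ces1 lay under the 25th percentile of the kidney arrays, so their sizes are uncertain.

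By limma 1825 genes changed in kidney, 863 up and 962 down, and 164 by at least 2-fold. With the wash station as a block, which rests on 1 SMA and 1 control array, 17 changed, 14 of them among the 1825. Of 299 genes called on the 4 kidney arrays outside that station, 95.3% had the same sign in the station's own pair, where 73.5% of all genes did. The count was 631 without SMA replicate 1, 829 without SMA replicate 2, 776 without SMA replicate 3, 789 without control replicate 1, 949 without control replicate 3 and 2123 without control replicate 2. It was 784 from medians of probe sets and 703 with no moderation. Groups did not overlap for 35.1% of genes, where chance gives 10%.

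Cell division genes fell almost as a whole in SMA kidney, 24 of 25 measured members over all genes and 25 adjusted over the list alone, with a median of -0.96. Plk1 (-1.32 ± 0.10), Aurka (-1.29 ± 0.12), Prc1 (-1.26 ± 0.11) and Ccna2 (-1.05 ± 0.09) were among them (camera adjusted p = 1.37e-18, and adjusted p = 0.196 with an estimated correlation). Of the glucocorticoid and fasting list 12 of 17 rose, and 13 adjusted over the list alone, with a median of 1.15, including Fkbp5, Angptl4, Sult1a1 (1.5 ± 0.11) and Tsc22d3 (1.37 ± 0.10). It was the 1 list of 9 called (adjusted p = 6.61e-15) that held with an estimated correlation (adjusted p = 0.0344). Of the cholesterol synthesis list 11 of 19 fell, and 12 adjusted over the list alone, among them Cyp51 (-1.14 ± 0.13), Sqle (-0.97 ± 0.11) and Mvd (-0.96 ± 0.09) (camera adjusted p = 1.15e-06, and adjusted p = 0.116 with an estimated correlation). Of the interferon list 8 of 20 fell (13 fell and 1 rose adjusted over the list alone), including Psmb9 (-0.71 ± 0.13) and Stat2 (-0.68 ± 0.09) (camera adjusted p = 3.45e-05, and adjusted p = 0.207 with an estimated correlation). Of the p53 target list 4 of 23 rose and 11 adjusted over the list alone, including the receptor gene Eda2r (1.48 ± 0.13, uncertain in size, with the control mean under the 25th percentile of the kidney arrays) (camera adjusted p = 1.83e-05, and adjusted p = 0.1 with an estimated correlation). Erythroid genes fell with Epo in these arrays, 3 of 6 by either adjustment, with Alas2, the erythroid heme synthesis enzyme gene, at -1.17 ± 0.11 (camera adjusted p = 0.0230, and adjusted p = 0.304 with an estimated correlation). Epb4.2 and Rhag of this list had both means under the 25th percentile of the kidney arrays, so their sizes are not reliable. Of the lymphocyte list 3 of 11 fell, also 3 adjusted over the list alone, including Cd8a (-0.97 ± 0.10, with the SMA mean under that percentile) (camera adjusted p = 0.0370, and adjusted p = 0.454 with an estimated correlation). Ms4a1 and Cd3g of the lymphocyte list had both means under that percentile, so their sizes are not reliable. Of the mitochondrial list 3 of 23 fell, and 5 adjusted over the list alone, with Cyc1 at -0.44 ± 0.10 (camera adjusted p = 0.00461, and adjusted p = 0.361 with an estimated correlation). Of the clock list 3 of 15 rose, also 3 adjusted over the list alone, with Per1 at 1.19 ± 0.12 (camera adjusted p = 0.00812, and adjusted p = 0.316 with an estimated correlation).

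Tubule genes changed in both directions in kidney. Of the proximal tubule list 6 of 29 rose and 10 fell, 7 and 11 adjusted over the list alone, and the list was not called (adjusted p = 0.505). Beside the rise of Cyp27b1, the organic anion transporter gene Slc22a6 fell by 1.57 ± 0.11, the phosphate transporter gene Slc34a3 by 1.16 ± 0.10 and the glucose transporter gene Slc5a2 by 0.95 ± 0.10. Of the list for loop, distal tubule and collecting duct 6 of 23 rose and 4 fell, 7 and 4 adjusted over the list alone (adjusted p = 0.112), with the water channel gene Aqp2 at 0.70 ± 0.13 and the calcium-binding protein gene Pvalb at -1.14 ± 0.13 (SMA mean under the 25th percentile of the arrays). The fibroblast and matrix list, with 1 rise and 1 fall among 17, was not called in kidney (adjusted p = 0.704). Markers of the neighbouring adrenal gland varied between control kidneys, with Cyp11a1 at 4.83 ± 0.92 (SD, n = 3) against 3.83 ± 0.08 in SMA, both under that percentile, and their list was not called (adjusted p = 0.444). In all 22 of 31 lists were not called, the nearest being podocyte (adjusted p = 0.0506), and 15 lists were called without control replicate 2. On wash station 1 the kidney medians were -0.95 for cell cycle, 1.16 for glucocorticoid and fasting, -0.57 for cholesterol, -0.48 for interferon, 0.26 for p53 targets, -0.54 for erythrocyte, -0.31 for lymphocyte, -0.16 for mitochondrial and 0.20 for clock genes. Signs of median, mean and camera direction differed for 4, 3 and 5 lists in spinal cord, brain and kidney, 0 of them called.

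**Figure D2:**
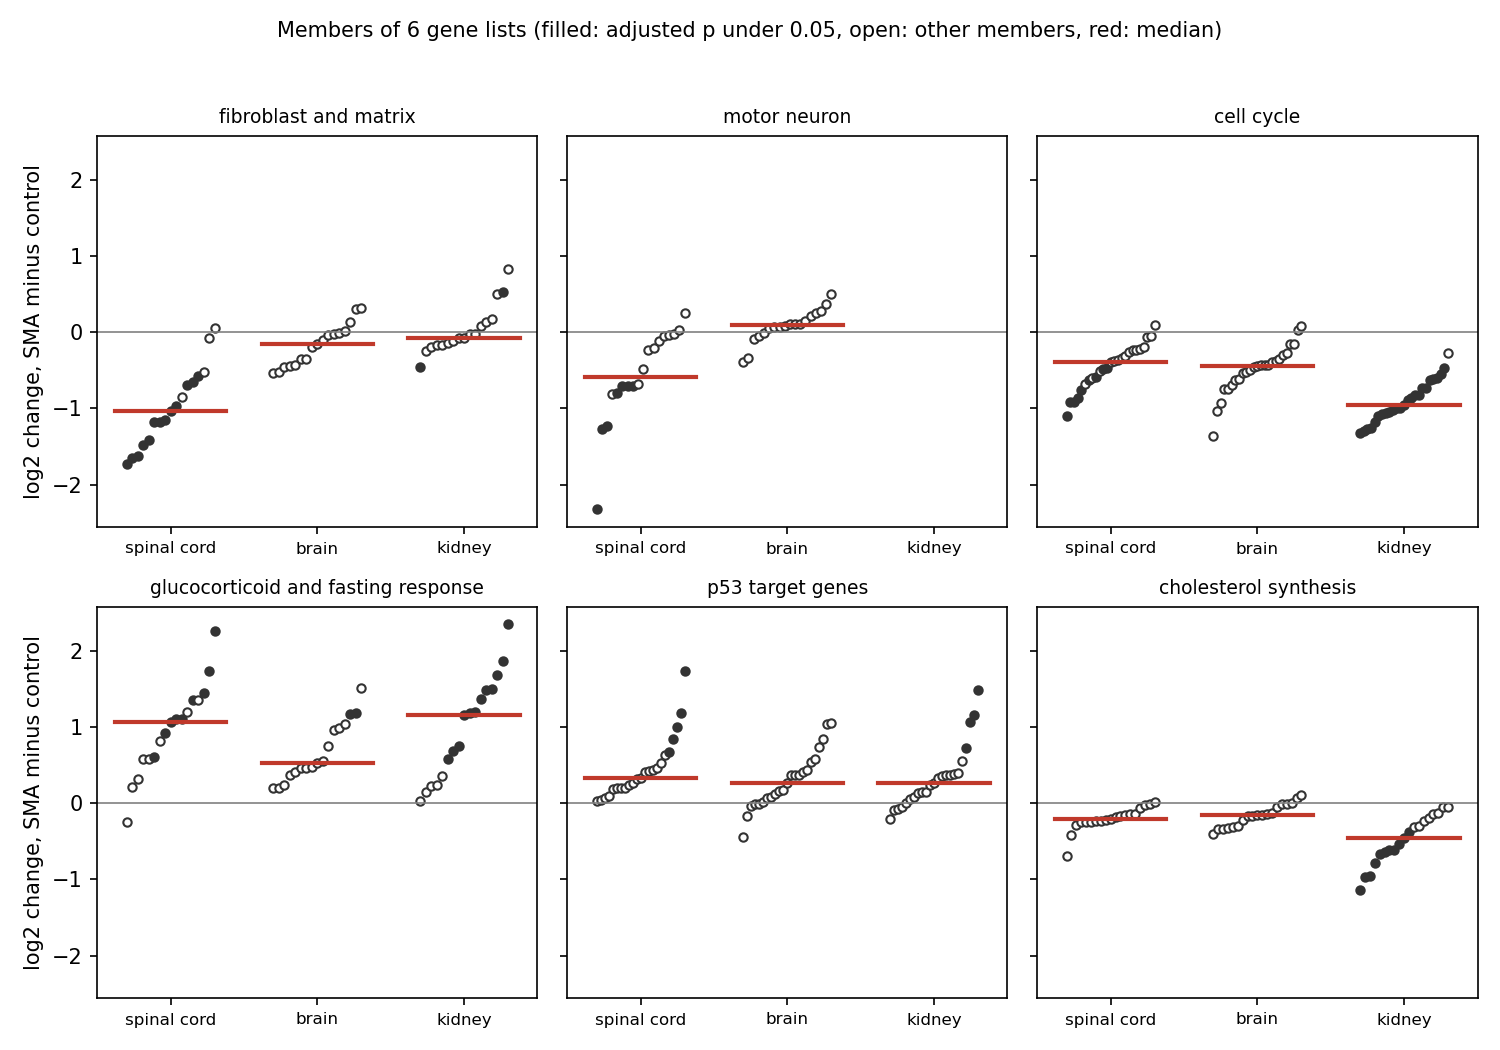
Log2 change, SMA minus control (vertical axis), of the members of 6 gene lists in spinal cord, brain and kidney (horizontal axis), with 1 point per gene sorted by change, filled where the adjusted p is under 0.05, and a red line at the list median. The fibroblast and matrix median is -1.04 in spinal cord, -0.16 in brain and -0.07 in kidney, and the cell cycle medians are -0.40, -0.44 and -0.96. The motor neuron list was not tested in kidney.

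At the level of single exons, 2 probe sets of Uspl1, a SUMO-specific peptidase gene, were higher in SMA than the rest of their gene. In spinal cord probe set 4482495 read 6.97 ± 0.22 (SD, n = 3) in SMA and 3.57 ± 0.20 in control, a relative change of 2.80 by diffSplice (adjusted p = 6.46e-06). The control mean lay at the 25th percentile of these arrays (3.48 to 3.60), near background, so the size is uncertain. In brain its relative change was 1.32, and that of probe set 4488579 was 1.93 (7.31 ± 0.31 against 5.04 ± 0.19, adjusted p = 7.32e-09 by diffSplice). The size of the latter is also uncertain, as the control mean lay under the 25th percentile (5.46 to 5.55). In kidney 4488579 had a relative change of 1.24 (adjusted p = 0.000261 by diffSplice). By the splicing index with a trend and robust prior, an alternative chosen after the data were seen, and adjusted over the list alone, 4482495 in spinal cord (2.61, adjusted p = 0.000925), 4488579 in brain (1.80, adjusted p = 0.00403) and probe set 5601266 of Agrn, which codes for agrin of the neuromuscular junction, in spinal cord (1.61, adjusted p = 0.0126) passed. These 2, 1 and 0 calls in spinal cord, brain and kidney were among 217, 211 and 162 probe sets of the list. At unadjusted p under 0.05 there were 18, 11 and 14, where chance gives 5% of the probe sets. Adjusted over all probe sets tested, 0 probe sets of the list passed in each tissue. The list was chosen from literature on SMA tissue, which can hold work on these samples, and is not independent evidence.

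**Figure D3:**
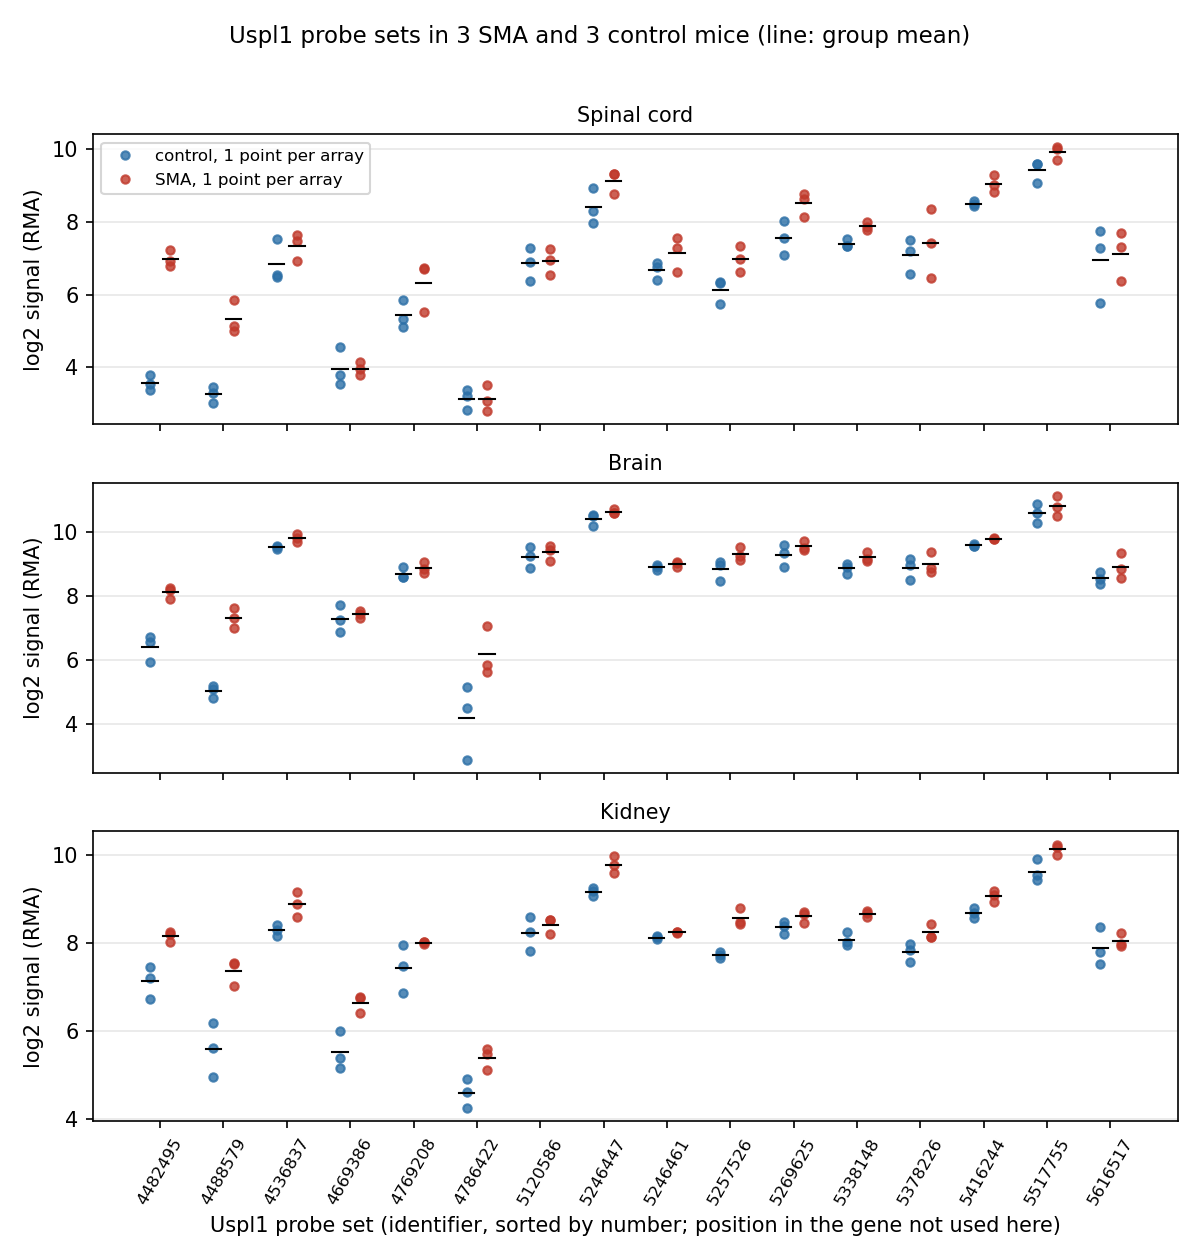
Log2 RMA signal (vertical axis) of the Uspl1 probe sets (horizontal axis, sorted by identifier) in spinal cord, brain and kidney, with 1 point per array, blue for control, red for SMA and a line at the mean of 3 arrays. Probe set 4482495 reads 6.97 in SMA and 3.57 in control spinal cord, and 4488579 reads 7.31 and 5.04 in brain.

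Other large relative changes by diffSplice lay in genes of several kinds. In spinal cord Fam107a probe set 4667975 had a relative change of -3.37, with a change of its own of -0.18 while its gene rose by 2.77, and Adcy9 5556339 (2.17), Ptpro 4732189 (2.13) and Rnpc3 4734116 (2.11), whose gene codes for a protein of the minor spliceosome, rose relative to theirs. In brain Scn3b 5058715 (1.46) rose and Nasp 4978095 (-1.53) and Ttr 5278467 (-1.33) fell relative to their genes. In kidney Cyp27b1 4855599 (-2.74) rose by 1.99, less than its gene, Fasn 4796393 (2.07) and Umod 4573567 (1.76) rose, and Rap1gap 4540249 (-2.45) fell, relative to their genes. The control arrays spread widely for Fasn (SD 1.69, against 0.03 in SMA), Rap1gap (1.09 against 0.40) and Umod (0.90 against 0.18), so these changes are uncertain. The lower group mean of Nasp 4978095, of Cyp27b1 4855599, and of these 3 kidney probe sets lay under the 25th percentile of their arrays. Over all genes diffSplice called 84 of 99821 probe sets in spinal cord, 61 of 99034 in brain and 534 of 99782 in kidney. On simulated data it called 343, 110 and 153 unchanged probe sets, in spinal cord and brain more than on the real arrays. These numbers are therefore not error rates of the real arrays. Other splits of the real arrays gave up to 512, 446 and 499 calls, so the real counts carry little weight. The splicing index called 1 (Fam107a 4667975), 0 and 2 (both Cyp27b1), with 4655, 3529 and 7529 at unadjusted p under 0.05. In spinal cord and brain these lie under 5% of the probe sets tested, the share that chance gives, and in kidney above it. On simulated data the index found 0%, 26.9% and 25.4% of probe sets changed by 1. Its few calls therefore do not show that changes of that size are absent. With the replicate block diffSplice called 308 in spinal cord, and with the wash station as a block 29 in brain and 1088 in kidney. Without SMA replicate 2, SMA replicate 3, control replicate 1, control replicate 2 or control replicate 3 it called 26, 145, 51, 55 and 200 in spinal cord. It called 21 and 25 in brain without SMA replicate 3 and control replicate 1. In kidney it called 227, 290 and 288 without SMA replicates 1, 2 and 3, and 269, 2310 and 334 without control replicates 1, 2 and 3. Called probe sets recurred between tissues, with 10 called the same way in at least 2 of them, in Uspl1, Per1, Scn3b, Fasn, Hecw2, Rgnef, Brd3 and Ephb3. For Fasn the control arrays disagreed in both tissues, with an SD of 1.83 in spinal cord and 1.69 in kidney, so its recurrence is uncertain. Same-direction overlaps were 2 for spinal cord and brain, 5 for spinal cord and kidney and 3 for brain and kidney, against 0.0130, 0.120 and 0.0945 for independent lists, and opposite overlaps were 0, 1 and 3. Brain and kidney thus had as many opposite as same-direction overlaps. The tissues may share mice and diffSplice was not calibrated, so independent lists are a weak standard here. The recurring probe sets of Per1, Fasn, Hecw2, Rgnef and Ephb3 had a relative change opposite in sign to the change of their gene, and those of Uspl1, Scn3b and Brd3 the same sign.

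Between spinal cord and brain the SMA effect differed most for motor neuron and matrix genes. Chodl had a change of -2.32 in spinal cord and 0.00 in brain, a difference of -2.32 ± 0.21 (SE) with an adjusted p of 3.77e-05 in limma. The matrix crosslinking enzyme gene Loxl1 differed by -1.17 ± 0.12 and Igfbp4 by -1.63 ± 0.20, both lower in SMA spinal cord. Agxt2l1 (-1.36 ± 0.14) had its rise in brain, Smtnl2 had values of -0.99 in spinal cord and 0.57 in brain, and the rise of Fkbp5 was larger in spinal cord by 1.30 ± 0.19. The fibroblast and matrix list differed by a median of -0.80 and the motor neuron list by -0.40, with adjusted p = 0.00568 and 0.0126 with an estimated correlation. In all 46 genes differed, 5 above and 41 below 0, and 1322 had an unadjusted p under 0.05. Regrouped arrays gave 46 or more genes in 10 of 100 splits, the real one included. The 9 others kept the real groups in 1 of the 2 tissues, and splits with the real groups in neither gave at most 7. Such splits do not test for equal effects in both tissues, so they cannot exclude chance for this count. The count was 73, 23 and 15 without SMA spinal cord replicates 1, 2 and 3, 24 and 11 without control spinal cord replicates 1 and 2, 30, 22 and 19 without SMA brain replicates 1, 2 and 3, and 16 and 30 without control brain replicates 1 and 3.

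The SMA effect in kidney differed from that in both nervous tissues. Cyp27b1, Hsd3b2, Osta, Rasgef1b and Abca6 were among the 6 genes with the smallest adjusted p in both pairs, with Gldc as the other one against spinal cord and 2410066E13Rik against brain. Cyp27b1 had values of 4.48 in kidney, -0.08 in spinal cord and 0.28 in brain. The change of the fibroblast and matrix list was lower in spinal cord than in kidney, where it was not called, by a median of -1.01 (adjusted p = 0.0107 with an estimated correlation). In all 810 genes differed between spinal cord and kidney and 864 between brain and kidney by limma. The second count was 575 without control brain replicate 1, 500 and 563 without SMA kidney replicates 1 and 2 and 464 without control kidney replicate 1. Medians of probe sets gave 348 and 251. Across genes, which are not independent replicates, changes correlated at r = 0.35 (rho 0.30) for spinal cord and brain, 0.24 (0.25) for spinal cord and kidney and 0.10 (0.06) for brain and kidney. Spinal cord and kidney shared 43 rising and 55 falling genes, where independent lists give 7.79 and 15.0, and 13 genes moved in opposite directions. If same-numbered arrays come from the same mice, the tissues also share each mouse's own deviations.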

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

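The test of centring and that of probe sets in genes changed by less than 0.5 were chosen after the results they measure had been seen, and the reading within single wash stations was added once the station block had proved void in spinal cord.

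Genes were marked for a closer look because the SMA effect differed between 2 tissues by a test of the difference itself: 46 between spinal cord and brain, 810 between spinal cord and kidney and 864 between brain and kidney. Between spinal cord and brain the named differences were Chodl -2.32, Agxt2l1 -1.36, Loxl1 -1.17, Igfbp4 -1.63, Smtnl2 -1.56 and Fkbp5 1.30. Between spinal cord and kidney they were Abca6 -2.01, Cyp27b1 -4.55, Hsd3b2 2.91, Osta 2.85, Rasgef1b -1.93 and Gldc -2.06. Between brain and kidney they were Hsd3b2 3.12, Abca6 -1.92, Cyp27b1 -4.19, Osta 3.06, Rasgef1b -2.02 and 2410066E13Rik -1.54. When the arrays of each tissue were regrouped freely, 3 of 100 splits gave as many genes for spinal cord and kidney (highest other 1112). For brain and kidney 4 of 100 did (highest other 1278). Such splits test for no SMA effect in either tissue, not for equal effects in both. They therefore cannot exclude chance for a difference between 2 effects. Over the 80 splits that keep the pairing of the spinal cord numbers, 2 gave as many for spinal cord and kidney (highest other 2474), and 20 for spinal cord and brain (highest other 1115). If the same number means the same mouse in 2 tissues, only 10 splits remain, too few for a share under 0.05, with highest other counts of 0, 2 and 9. For spinal cord and brain 10 of 100 splits gave 46 or more (highest other 386), so chance could not be excluded. Of the 100 splits, all as large kept the real groups in 1 of the 2 tissues, and splits with the real groups in neither gave at most 7, 2 and 34 genes.

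Probe sets with no gene symbol or with several, which the comparisons did not use, were marked because 4 of 14703 changed in kidney by limma, 1 up and 3 down, with 2127 at unadjusted p under 0.05. In spinal cord and brain 0 changed, with 1269 and 909 at unadjusted p under 0.05.

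Within a tissue the 6 arrays make 10 splits, too few for a share under 0.05. For genes, 1 split of 10 in each tissue, the real one, gave as many as the real 387, 6 and 1825, and the highest other counts were 0, 0 and 1. In spinal cord 4 splits part all 3 pairs of numbers, and the others of these gave at most 0 genes, 11 lists and 150 probe sets, against the real 387, 12 and 84. For gene lists, 2, 1 and 3 splits gave as many as the real 12, 11 and 9 (highest other 14, 6 and 11). For probe sets by diffSplice, 7, 5 and 1 splits gave as many as the real 84, 61 and 534 (highest other 512, 446 and 499). In spinal cord and brain other splits called several times the real number of probe sets. In spinal cord, where same-numbered arrays deviated together, the 512 came from a split that parts 1 of the 3 pairs of numbers. What lies behind the brain splits was not tested, and diffSplice also called 343 and 110 unchanged probe sets on simulated data.

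Matrix genes fell in SMA spinal cord, with a fibroblast and matrix median of -1.04. The wash station was argued against as the whole cause, because at least 96.6% of the median stayed within each station, with 16 of 17 genes lower on station 2, which held 2 arrays per group (station 1 held 1), while the block kept 100% by the balance of the design and decides nothing. Less meningeal tissue left on the SMA cords stays open. Of 19 other meningeal genes 17 were lower and 6 fell, including Pcolce (-1.26) and Islr (-0.97), with a median of -0.42 (camera p = 1.10e-09, and p = 0.0612 with an estimated correlation). A lower output of matrix genes by the same cells and fewer such cells in the tissue cannot be told apart from it here, since dissection was not recorded in the sources used here.

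The cell cycle list was called down in all 3 tissues at the preset correlation, with medians of -0.40, -0.44 and -0.96, but in none with an estimated correlation (adjusted p = 0.0983, 0.210 and 0.196), and 0 of 25 members passed in brain. Centring kept at least 96.3% of the medians and decides nothing on a shift by normalization, since the array medians were already equal. In spinal cord at least 97.5% of the median stayed within each wash station, and station 2, with 2 arrays per group, gave -0.40 (23 of 25 lower), against the station as the whole cause there, while the block kept 100% by the balance of the design. In brain and kidney most SMA arrays were washed on a station that held no control array, and the pair on the shared station gave -0.53 (22 of 25 lower) and -0.95 (25 of 25 lower), values from 1 array per group that have no spread and leave the station open there. Slower growth of the SMA mice may contribute and was not tested.

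Probe sets that changed relative to their gene in kidney may in part reflect probe sets that respond less than their gene. Genes changed by 0.5 or more held 26.0% of called and 8.76% of tested probe sets in kidney. In spinal cord they held 31.0% and 5.90%, and in brain 8.20% and 1.30%. Called kidney probe sets had a median level of 6.99, and tested ones 8.91. Whether probe sets moved against their gene was examined as follows in kidney alone. In genes changed by 0.5 or more, 67.6% of 139 called probe sets had a relative change opposite in sign to the change of their gene, where 49.0% of all tested did, and the explanation stays open there. In genes changed by less than 0.5, 37.7% of 395 did. The gene's change includes the called probe set itself, which pulls both to the same sign in a gene that barely moves. This share therefore decides nothing, and the explanation stays open there too. No biological explanation was tested for these probe sets.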

How the results depend on the processing

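The wash station block and the splicing index with a trend and robust prior were chosen after seeing the data, and the other alternatives were planned. A block on the hybridisation day was planned and not run, since all arrays of a tissue share a day. Except where fewer arrays, genes or probe sets entered the test, the cause of a difference was not tested. In each group of values spinal cord comes first, then brain, then kidney, and all counts are by limma at an adjusted p of 0.05. Counts of genes were 54, 1 and 784 from medians of probe sets, 7, 0 and 703 with no moderation, 1090, 0 and 1149 with the replicate block and 209, 1 and 17 with the wash station as a block. All 18 arrays in one model gave 913 in spinal cord and 187 in brain. Brain gave 0 from probe sets above the 25th percentile, 31 from genes at or above the median gene and 41 with a mean-variance trend and robust prior. Smn1 kept its direction throughout and lost its call with the station block (-0.92, -1.37 and -1.44), and in brain with medians (-2.08), probe sets above the 25th percentile (-0.67) and the replicate block (-1.78). With an estimated correlation 4, 1 and 1 lists were called, and with fry in either direction 23, 22 and 28. Probe set counts were 1, 0 and 2 by the splicing index and 1, 0 and 5 with its trend and robust prior. They were 339, 218 and 885 with no filter on dim genes and 41, 4 and 169 above the median probe set. In genes changed by less than 0.5 they were 54 in spinal cord and 354 in kidney. With the replicate block they were 308 in spinal cord and 24 in brain, and with the station block 29 in brain and 1088 in kidney. Genes differing between tissues by medians of probe sets were 21 for spinal cord and brain, 348 for spinal cord and kidney and 251 for brain and kidney. For spinal cord and brain they were 70 at or above the median gene in either tissue and 13 from the 12 arrays of both tissues alone. With 1 array left out, genes ranged from 60 to 273, 0 to 8 and 631 to 2123, lists from 11 to 13, 9 to 12 and 9 to 15, and probe sets from 26 to 200, 21 to 75 and 227 to 2310. Tissue differences then ranged from 11 to 73, 568 to 907 and 464 to 1145 for spinal cord and brain, spinal cord and kidney, and brain and kidney. Smn1 ranged from -1.05 to -0.82, -1.92 to -1.63 and -1.61 to -1.44. With the station block Cox7a2 in brain (-0.0145) and Trmt1 probe set 5531151 in kidney (0.37) reversed in sign. For named genes, named probe sets and named tissue differences, 3147 values kept direction and side of the threshold, 652 lost the call and 67 gained it. The replicate block changed no other main result of the spinal cord. Signal over background limits the exon results in that both filters on dim probe sets moved their counts, and its share among the limits was not tested.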

Other observations

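The test of Smn1-linked variants was written before its result, as were those of heat shock genes and of fatty acid genes.

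Cirbp, the cold-inducible RNA-binding protein gene, rose in spinal cord (1.24) and kidney (1.51) and had a value of 0.90 (adjusted p = 0.0589) in brain. A lower body temperature of the SMA mice may raise it. Heat shock genes, which would then fall, moved down by camera in 2 tissues, with medians of -0.33, -0.08 and -0.24 in spinal cord, brain and kidney (p = 0.00102, 0.00768 and 0.206, and 0.107, 0.109 and 0.399 with an estimated correlation). Rbm3, the other common cold-induced gene, was not measured, so the explanation stays open.

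Cyp4a14, Ehhadh and Angptl4, targets of the fatty acid receptor PPAR-alpha, rose in SMA kidney. Fasting-like lipid use may explain this as a hypothesis. Of 16 other PPAR-alpha targets 13 were higher and 5 rose, including Cyp4a10 (0.89) and Acot1 (0.85), with a median of 0.33 (camera p = 3.27e-05, and p = 0.0199 with an estimated correlation). Food intake was not recorded in the sources used here.

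Probe sets called the same way in at least 2 tissues might reflect sequence variants linked to the Smn1 locus that alter probe binding. Of the 8 genes with such probe sets 1, Rgnef, lies among the 100 genes on either side of Smn1, which argues against linkage as the main cause. Of 15402 matched genes 143 lie there, a smaller share, so linkage stays open for Rgnef itself. Among measured neighbours 5, 0 and 19 genes were called in spinal cord, brain and kidney, where 3.52, 0.0546 and 16.6 are expected (Fisher exact p = 0.406, 1 and 0.512). Of their probe sets 1, 2 and 8 were called by diffSplice, where 0.948, 0.731 and 5.87 are expected (Fisher exact p = 0.615, 0.166 and 0.398).

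The Y-linked gene Eif2s3y read 7.27, 9.08 and 9.28 in SMA replicate 2 of spinal cord, brain and kidney and 6.71, 8.77 and 8.06 in control replicate 1, and at most 3.39 in every other array. Each group therefore held 1 array with Y-linked signal, under the same number in each tissue. Control replicate 1 was also the control array on wash station 1, beside SMA replicate 3, which had no Y-linked signal. Values from within station 1, and station blocks in brain and kidney, therefore also compare the sexes. The array files of the spinal cord name skeletal muscle as the sample type. On the same probe sets, neuron markers averaged 9.63 in control spinal cord and 5.27 in control kidney, whose arrays have the higher medians, and skeletal muscle markers averaged 4.52 and 5.39.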
